A study of Mus musculus with 2 samples.

How the data were processed

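H3K4me2, histone H3 dimethylated at lysine 4, was measured by chromatin immunoprecipitation followed by sequencing (ChIP-seq) in the neural tube of mouse embryos at embryonic day 15.5. Per the labels, the tissue came from strain B6NCrl embryos of both sexes, and each of the 2 biological replicates was a separate pool, of 78 embryos for replicate 1 and of 62 embryos for replicate 2. The labels give 1 group and no treatment, so the only comparison between samples is replicate 1 against replicate 2, and every other comparison is between sets of genes or positions within these libraries.

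Per the text deposited with the files, peaks were called on the alignments of each replicate with that replicate's own control and on the pooled alignments of both replicates. Per the same text, a replicated list was derived from these 3 peak lists. The build was mm10, per the labels. The aligner, the peak caller and their versions are not given in the sources used here. Each peak carries the authors' fold enrichment, a ratio of ChIP over control at the peak, as deposited. Each peak also carries the authors' −log10 p and −log10 q, as deposited. The lowest −log10 p was 2.01 in replicate 1 and 2.16 in replicate 2. The −log10 p of the pooled and replicated lists was not used here. Fold enrichments were the peak caller's own values. They were used to describe, rank or filter peaks, to correlate overlapping peaks of the replicates, and to compare X with autosomal promoters within a list. The read depth behind the peaks is unknown from these files, so no value carries a counting interval, and a gene without a peak may hold signal below the caller's threshold.

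Peaks on chromosomes 1 to 19, X and Y were kept, and those on unplaced scaffolds were left out of the comparisons (18 in replicate 1, 19 in replicate 2, 18 in the pooled list and 14 in the replicated list). All peak ends lay within the chromosome lengths of GRCm38, the assembly that mm10 names. Genes came from the GENCODE M21 annotation of that assembly, with 21938 protein-coding genes on the chromosomes used. A promoter was called occupied where a peak lay within 1 kb of any annotated transcription start site (TSS) of the gene. The covered length of a gene was the number of bases under peaks within 5 kb either side of its representative TSS (10001 bp in all), averaged over the 2 replicates. The representative TSS was the position shared by most annotated transcripts, with ties going to the most 5' one. For some genes this was an alternative start away from the occupied promoter: Map2 and Mbp had a covered length of 0.00 kb although another of their TSSs carried a peak. A distal peak lay over 2.5 kb from every protein-coding TSS and was assigned to the nearest one within 100 kb.

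Before the data were examined, 21 lists with 356 genes between them were fixed for cell types and regional identities of the neural tube, for other tissues and for housekeeping, and the olfactory receptor genes were added as the 22nd list. That list had 1134 symbols and 1135 genes, because Olfr290 has 2 gene identifiers in the annotation. All fixed symbols were found in the annotation, with Drgx matched through its other symbol Prrxl1. Genes named in the text followed a rule fixed at the same time. In each list these were the 3 members with the largest covered length and the first 2 in alphabetical order with no peak within 1 kb of a TSS in either replicate. Outside the lists they were the 10 genes with the widest promoter peak, the 5 peaks of the highest fold enrichment, and per replicate the 3 genes of the highest fold enrichment among promoters with a peak in that replicate only. The Hox clusters were the last part of the rule, and genes named outside it are marked as such.

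Occupancy of a list was set against all other protein-coding genes with a two-sided Fisher's exact test. Covered length and distal peaks were tested two-sided against 100000 random gene lists of the same size. For distal peaks the random lists were matched on the decile of the gene's territory length. The territory was all sequence nearer to the gene's TSSs than to any other protein-coding TSS, up to 100 kb on each side of a TSS. Differences between 2 lists were tested with two-sided permutation tests of 100000 resamples and carry 95% bootstrap intervals over genes. The smallest p these permutations can give is 1e-05. P-values of list tests, of the 3 differences and of the 4 microRNA tests were adjusted by the Benjamini-Hochberg method within each of these families, with a threshold of 0.05. P-values of peak location and of the Fisher's exact tests on the widest and strongest promoters were not adjusted. Peak locations were set against 100 random placements on the same chromosome, for which the smallest p is 0.0099. Genes are not independent replicates, so these tests describe the 2 libraries and not a population of embryos.

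The permutation tests were tested on simulated data made from the 21938 real covered lengths. With no change, 5.6% of 1000 random lists of 14 genes passed p below 0.05, and with 1000 bp or 2000 bp added to each member 50.8% and 98.7% did. Random lists of 14 genes drawn from CpG-rich promoters passed in 91.0% of runs against all genes and in 4.9% against lists matched on CpG content, so results for covered length and occupancy are also given against matched lists. Distal peaks and microRNA loci were not matched on CpG content. The difference test of 48 against 32 genes passed in 5.6% of runs without a change and in 99.9% with 2000 bp added. Counts of covered bases matched a brute-force count in 2000 of 2000 simulated windows.

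Alternatives fixed before the data were examined were a stricter threshold (−log10 q of at least 2), other windows and overlap rules, the authors' pooled and replicated lists in place of the replicates, each replicate left out, and random lists matched on CpG content. Alternatives added later were occupancy against random lists matched on CpG content, the TSS with the largest covered length of each gene, the genes with no other protein-coding TSS within 5 kb, and the spinal cord factors without their 5 members of the largest covered length. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and numba 0.67.0, and figures used matplotlib 3.10.9.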

Results

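H3K4me2, a histone mark found at promoters and enhancers, was mapped in the neural tube of mouse embryos at embryonic day 15.5, when the spinal cord holds late progenitors, differentiating neurons and the first glia. The 2 samples form 1 group of 2 biological replicates, pools of 78 and 62 embryos of both sexes. Replicate 1 had 50867 peaks and replicate 2 had 52151 (51509 ± 908, SD, n = 2), which covered 58.7 Mb and 59.5 Mb of the genome. The authors' list called on both replicates together held 56423 peaks, and their replicated list held 40020. Median peak width was 623 bp and 625 bp in the replicates, 632 bp in the pooled list and 1025 bp in the replicated list. Sequencing depth is unknown, so a missing peak does not show that the mark was absent.

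The first question was how far the 2 pools gave the same regions. At promoters they differed little: 14914 genes had a promoter peak in both replicates, 120 in replicate 1 only and 99 in replicate 2 only. Among the promoters with a peak in replicate 1 only, the highest fold enrichments were at Pglyrp1 (50.3), Hcst (48.3) and 1700086D15Rik (34.2). Among those with a peak in replicate 2 only they were at Amh (48.3), the apolipoprotein gene Apoa1 (36.9) and the vasopressin gene Avp (16.5). All 6 genes had peaks of both replicates in the 10 kb around the representative TSS, from 1.23 ± 0.0247 kb at Pglyrp1 to 3.59 ± 0.277 kb at Amh (SD, n = 2), so the replicates differed there in how near to a TSS the peaks reached.

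Over the whole genome, 41986 of the 50867 peaks of replicate 1 (82.5%) shared at least 1 bp with a peak of replicate 2, and 42077 of the 52151 peaks of replicate 2 (80.7%) did so in the other direction. The mean was 81.6%, and the SD of 1.31% is over the 2 directions of the same comparison, not over replicates. Unshared peaks were weak and narrow. The 8881 peaks of replicate 1 without a partner had a median fold enrichment of 3.08 and a median width of 240 bp, against 9.34 and 850 bp for its shared peaks. In replicate 2 the 10074 unshared peaks had 3.15 and 245 bp, against 9.57 and 874 bp. Promoters were rarer among unshared peaks, with 11.9% and 9.50% within 1 kb of a TSS in replicates 1 and 2 against 43.8% and 44.3% of shared peaks. All peaks with a fold enrichment of 10 or more were shared, in both replicates. Across the 41986 overlapping pairs of peaks, fold enrichment in the 2 replicates correlated with a Spearman rho of 0.839 and, on the log2 scale, a Pearson r of 0.87, and these are correlations across peaks, which are not independent replicates.

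**Figure D1:**
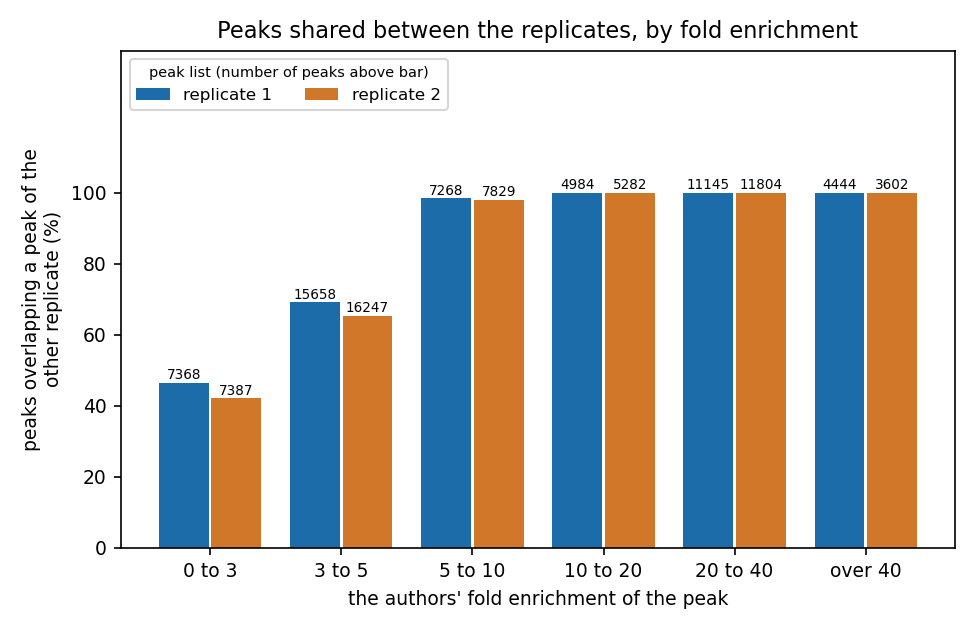
Share of the peaks of each replicate that overlap a peak of the other by at least 1 bp (y axis, percent), in bins of the authors' fold enrichment (x axis), with the number of peaks above each bar. The share was 46.4% and 42.1% for peaks under a fold enrichment of 3, 98.5% and 98.0% from 5 to 10, and 100% in each bin from 10 upward.

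Most protein-coding genes carried H3K4me2 at a promoter. In replicate 1 the promoters of 15034 of 21938 genes (68.5%) were occupied and in replicate 2 those of 15013 (68.4%), a mean of 68.5 ± 0.0677% (SD, n = 2). Occupancy followed the CpG content of the promoter, from 4.42% of genes in the lowest decile of CpG observed over expected to 99.6% in the highest, in the replicated list. The strongest peaks of that list lay at the promoters of Adgrg6, an adhesion G protein-coupled receptor gene (chromosome 10, 14543669 to 14546494, fold enrichment 82.5), and E2f8, a cell cycle regulator (chromosome 7, 48880346 to 48882812, 82.5). Rreb1 (82.3), Col27a1 (81.4) and Emilin2 (79.8) followed. All 5 of these peaks were between 2.30 and 3.98 kb wide.

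Promoters held 43.3% of the 40020 replicated peaks (17337), gene bodies 26.5% (10611) and intergenic space 30.2% (12072). These classes used protein-coding genes only. Of the intergenic peaks 1586 (13.1%), and of the gene body peaks 495 (4.66%), lay near a TSS of another gene. Random placements put 6.52% of peaks at promoters, so promoters held 6.65 times the random share, while gene bodies held 0.730 times and intergenic space 0.528 times theirs (permutation p = 0.0099 for each, the smallest that 100 placements can give). Promoter peaks were the wide and strong ones, with a median width of 2281 bp and a median fold enrichment of 34.1. Gene body peaks had 633 bp and 4.42, and intergenic peaks 688 bp and 5.98. Counted by covered bases, promoter peaks made up 69.8% of the replicated list, 8.13 times the random share. On that count gene bodies held 0.380 times and intergenic space 0.300 times theirs.

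Gene lists fixed before the data were examined then asked whether genes of the neural tube carried the mark more often than other genes. In the replicated list, all 14 neural progenitor genes, all 16 pan-neuronal genes and all 15 transmitter genes had an occupied promoter, as did all 27 Hox genes of paralogue groups 1 to 9 and all 12 of groups 10 to 13. Of the factors that pattern the dorsoventral axis 21 of 22 were occupied, with Dbx1 the exception, and of the spinal neuron factors 25 of 26, with Evx2 the exception. Factors of the forebrain and midbrain did not stand apart, with 23 of 24 occupied and only Otx2 without a promoter peak, and all 25 housekeeping genes were occupied. These 9 lists were above the other genes, of which about 68.1% were occupied (adjusted p from 0.000218 to 0.0233, two-sided Fisher's exact test over 22 lists). Against random lists matched on CpG content only the Hox genes of groups 1 to 9 still passed among these 9 (100% against 88.4%, adjusted p = 0.0477, permutation test; range over 6 alternatives 0.000218 to 0.0477). Hox genes of a cluster share peaks and are not independent, so that p-value overstates the evidence. The matched lists of the other 8 were themselves occupied at 83.3% to 96.8%, and the adjusted p-values were 0.0534 to 1.00 (permutation test). So near to 100%, short lists had little room to pass.

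Before matching, 4 lists fell below the other genes. Of 13 microglia and macrophage genes, P2ry12 alone was occupied, and of 13 liver and gut genes Apoa1 alone (7.69% each, adjusted p = 7.34e-05, Fisher's exact test). The peak at P2ry12 was weak, with a fold enrichment of 2.86 and a width of 547 bp. Of 12 erythroid genes, 4 were occupied (Gypa, Klf1, Nfe2 and Tal1; adjusted p = 0.0407, Fisher's exact test). Of 1135 olfactory receptor genes Olfr94, Olfr658 and Olfr1033 were occupied (0.264%). P2ry12, Gypa, Olfr658 and Olfr1033 were named after their values were seen. The other 9 lists did not pass: astrocyte 11 of 13, mural and meningeal 10 of 12, ganglion and Schwann cell 12 of 15, non-neural developmental factors 25 of 32, endothelial 9 of 13, oligodendrocyte 9 of 14, epidermal 7 of 12, muscle 6 of 13, and germ cell and pluripotency 5 of 13. The germ cell list had an adjusted p of 0.0522 and passed without replicate 2, in the pooled list and with promoters of 2.5 kb, and against lists matched on CpG content (82.03% expected; adjusted p 0.00011 to 0.0522 over 6 alternatives, Fisher's exact and permutation tests). The mural and meningeal list passed in the pooled list, where all 12 genes were occupied (adjusted p = 0.0368, range over 6 alternatives 0.0368 to 0.440, Fisher's exact and permutation tests). Against matched lists the astrocyte list passed (58.6% expected; adjusted p = 0.0477, permutation test; range over 6 alternatives 0.0477 to 0.452). The microglia, liver and gut, and erythroid calls ended there (adjusted p = 0.0657, 0.0657 and 1.00, permutation test; lowest over 6 alternatives 5.4e-05, 3.24e-06 and 0.0217), and the olfactory receptor genes stayed lower (11.1% expected). The erythroid call also ended with promoters of 2.5 kb (adjusted p = 0.0815, Fisher's exact test).

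The length of sequence under the mark separated the lists further. Within 5 kb either side of the TSS, the mean protein-coding gene had 2.03 kb under peaks. Hox genes of groups 1 to 9 had 8.72 ± 0.0454 kb (SD, n = 2 replicates, here and below), pan-neuronal genes 5.80 ± 0.104 kb, Hox genes of groups 10 to 13 5.73 ± 0.0818 kb, transmitter genes 4.996 ± 0.125 kb and neural progenitor genes 4.79 ± 0.0156 kb. Spinal neuron factors had 4.19 ± 0.0795 kb, dorsoventral factors 3.65 ± 0.0383 kb, housekeeping genes 3.51 ± 0.0426 kb and astrocyte genes 3.37 ± 0.0173 kb. All 9 lists were above random lists of the same size (adjusted p from 3.14e-05 to 0.0168, permutation test over 22 lists), and all but the dorsoventral factors were also above lists matched on CpG content (adjusted p from 4.4e-05 to 0.0413, permutation test).

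The genes named here are the most covered members of each list, and members of a list differed. Spinal neuron factors had a median of 2548.5 bp, below their mean. Among them, the window of 10 kb was fully under peaks at Lhx1 and Tlx3 and almost so at Lmx1b (9.92 ± 0.0240 kb). Among transmitter genes, Slc32a1, the vesicular transporter of GABA and glycine, had 9.81 ± 0.0658 kb, Gad1, which makes GABA, 9.03 ± 0.357 kb and the glycine transporter gene Slc6a5 8.08 ± 0.204 kb. The RNA-binding protein genes Elavl4 (8.81 ± 0.0714 kb) and Celf4 (8.04 ± 0.219 kb) and the neuronal tubulin gene Tubb3 (7.24 ± 0.672 kb) led the pan-neuronal list. The Notch targets Hes5 (7.18 ± 0.0509 kb) and Hes1 (7.04 ± 0.224 kb) and the glial competence factor Sox9 (6.91 ± 0.127 kb) led the progenitors. Irx3 (7.55 ± 0.0707 kb), Nkx6-1 (6.76 ± 0.787 kb) and Ascl1 (6.16 ± 0.00778 kb) led the dorsoventral factors. The housekeeping genes with most coverage were Polr2a (6.49 ± 0.0530 kb), Ubc (5.73 ± 0.0488 kb) and Chmp2a (5.40 ± 0.0721 kb).

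Glial lists were uneven. The gliogenic factors Nfib (9.78 ± 0.0113 kb), Id3 (7.21 ± 0.00212 kb) and Nfia (6.08 ± 0.0269 kb) led the astrocyte list, whereas Gfap, the filament gene of mature astrocytes, and Agt had no bases under peaks in either replicate. Fgfr3 (5.66 kb), Glul (5.42 kb), Gja1 (5.02 kb) and Aldoc (4.24 kb) were also covered, and S100b (0.344 kb) and Aqp4 (0.123 kb) little. Slc1a2 and Aldh1l1 had 0.00 kb although another of their TSSs carried a peak. These other members were named after their values were seen. Pdgfra, the receptor gene of oligodendrocyte precursors, had 7.79 ± 0.464 kb, Cspg4 4.46 ± 0.286 kb and Cnp 4.10 ± 0.332 kb, while the myelin gene Mag had 0.00 kb and Gpr17 1.57 ± 0.989 kb. The oligodendrocyte list as a whole, at 2.11 ± 0.0545 kb, was not above random lists (adjusted p = 0.919, permutation test). The astrocyte call ended when the window was narrowed to 2.5 kb either side (adjusted p = 0.585, permutation test, range over 10 alternatives 5.5e-05 to 0.585). With each gene's most covered TSS the astrocyte mean was 4816 bp, against 2195 bp in random lists (adjusted p = 5.5e-05, permutation test).

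Among the other lists, 6 had a lower covered length than random lists. Olfactory receptor genes had 0.00624 ± 0.000298 kb, liver and gut genes 0.320 ± 0.00538 kb, germ cell and pluripotency genes 0.354 ± 0.0277 kb, microglia and macrophage genes 0.614 ± 0.0355 kb, erythroid genes 0.670 ± 0.00312 kb and muscle contractile genes 0.854 ± 0.0369 kb (adjusted p from 3.14e-05 to 0.0330, permutation test). Of these, only the olfactory receptor and the germ cell lists were also below lists matched on CpG content (adjusted p = 4.4e-05 and 0.00011, permutation test). Afp and Ahsg of the liver, Myh3 of muscle, Ddx4 and Mael of germ cells, Aif1 of microglia and Alas2 of red cells had 0.00 kb in both replicates. The 3.91 ± 0.334 kb at Cd68, the 2.35 ± 0.0219 kb at Acta1 and the 2.46 ± 0.116 kb at Apoa2 lay over 1 kb from every TSS of these genes. The remaining 6 lists did not pass (adjusted p from 0.0997 to 0.982, permutation test): epidermal 1.07 ± 0.0478 kb, non-neural developmental factors 1.54 ± 0.0927 kb, endothelial 1.55 ± 0.0982 kb, forebrain and midbrain factors 2.03 ± 0.243 kb, mural and meningeal 2.21 ± 0.280 kb, and ganglion and Schwann cell 2.33 ± 0.0120 kb. The most covered members were Grhl3 (2.62 ± 0.0764 kb) among epidermal genes, Esam (3.89 ± 0.293 kb) among endothelial genes, Foxc1 (5.30 ± 0.851 kb) among mural and meningeal genes and Foxd3 (5.59 ± 0.168 kb) among ganglion and Schwann cell genes.

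CpG content moved these list results. Against random lists matched on it, the calls of 5 lists ended: dorsoventral factors (adjusted p = 0.128, permutation test, as for all that follow), microglia and macrophage (0.839), erythroid (0.513), muscle (0.513) and liver and gut (0.299). Each of these p-values was the highest over 10 alternatives, whose lowest were 5.5e-05, 8.8e-05, 0.00424, 0.00918 and 0.000283 in the same order of lists. The forebrain and midbrain factors and the non-neural developmental factors then lay below the matched lists, with differences of −769 bp (adjusted p = 0.0205, range over 10 alternatives 0.0205 to 0.949) and −933 bp (adjusted p = 0.00139, range 0.00139 to 0.618) in the permutation test. With 2.5 kb either side the non-neural developmental factors (adjusted p = 0.0295) and the epidermal genes (adjusted p = 0.0196, range over 10 alternatives 0.0196 to 0.356) were also lower by the permutation test. With a window of 10 kb either side the microglia (0.0768), erythroid (0.201) and muscle (0.0568) calls ended, the erythroid call ended among genes without a neighbouring TSS within 5 kb (0.0837), and the dorsoventral call ended when peak width replaced covered length (0.116).

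**Figure D2:**
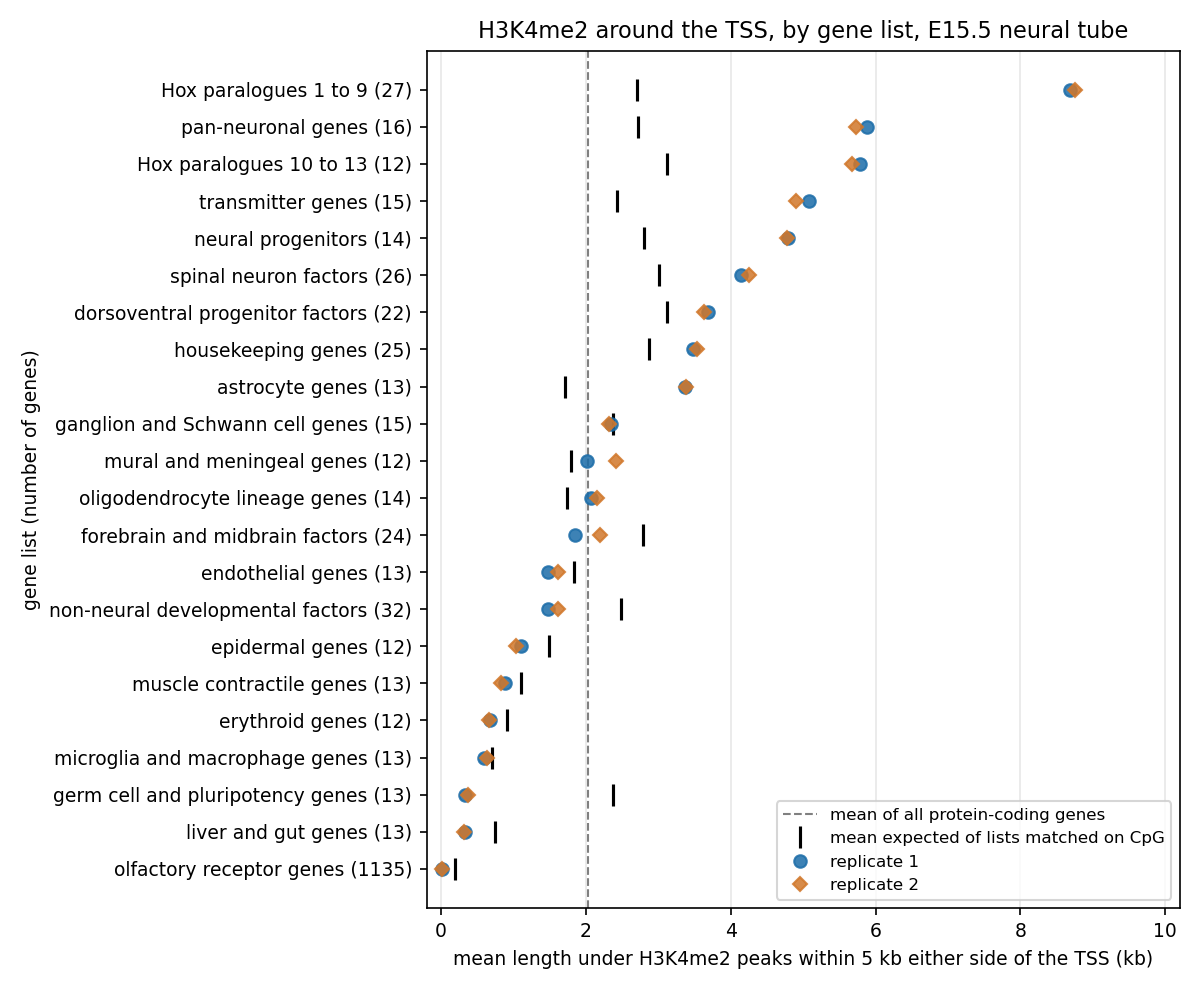
Mean length under H3K4me2 peaks within 5 kb either side of the TSS (x axis, kb) for each fixed gene list (y axis, number of genes in brackets), with 1 point per replicate, the mean of all protein-coding genes as a dashed line and the mean of lists matched on CpG content as black ticks. Hox genes of groups 1 to 9 lie highest, near 8.72 kb, and olfactory receptor genes lowest, near 0.00624 kb, with the points of both replicates close together in every list.

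The labels give the tissue as neural tube, so transcription factors of the spinal cord were compared with developmental factors used elsewhere. The 48 dorsoventral and spinal neuron factors had a mean of 3946 bp under peaks, against 1545 bp for the 32 non-neural developmental factors, a difference of 2401 bp (95% bootstrap interval 1476 to 3325; adjusted p = 0.00018, permutation test over a family of 3). Replicates 1 and 2 gave 2449 bp and 2354 bp. Prrx1, a limb and mesenchyme factor (5.83 ± 0.512 kb), Shox2 (4.35 ± 0.131 kb) and Tbx6 (4.21 ± 0.251 kb) were the most covered of the non-neural factors, and the hepatic factor Hnf4a had 0.00 kb and Hnf1a 0.247 ± 0.349 kb.

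The list of factors of more anterior brain regions also had shorter coverage than the spinal cord factors. No forebrain or midbrain tissue was profiled, so this is a difference between gene lists and not between regions. The 24 forebrain and midbrain factors had a mean of 2025 bp, 1920 bp less than the spinal cord factors (95% bootstrap interval of the difference 989 to 2905; adjusted p = 0.00255, permutation test), with differences of 2074 bp and 1767 bp in the replicates. Neurod2 (5.75 ± 0.0771 kb), Neurod6 (5.13 ± 0.386 kb) and Pitx3 (3.45 ± 0.146 kb) had the largest coverage of that list, and Otx2, a factor of the forebrain and midbrain, had 0.00 kb. Both differences passed under all 11 alternatives, with adjusted p-values from 6e-05 to 0.0058 and from 0.00138 to 0.0173 (permutation tests). With matching on CpG content the differences were 1686 bp and 1504 bp. Without the 5 most covered spinal cord factors the differences were 1717 bp and 1236 bp. They changed with the length of the window, from 1429 bp and 1026 bp at 2.5 kb either side to 3696 bp and 3055 bp at 10 kb.

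Hox genes, which encode position along the body axis, lay under the widest peaks of the data. The widest replicated peak spanned 78.9 kb of the Hoxb cluster (chromosome 11, 96268553 to 96347477) and covered the TSSs of Hoxb3, Hoxb4, Hoxb5, Hoxb6, Hoxb7, Hoxb8 and Hoxb9, and single peaks of 78.3 kb and 78.6 kb met it in replicates 1 and 2. A peak of 28.3 kb in Hoxa (chromosome 6, 52199974 to 52228241) covered the representative TSSs of Hoxa3, Hoxa5, Hoxa6, Hoxa7 and Gm28308. Peaks of 26.6 kb in Hoxd (chromosome 2, 74703212 to 74729774) and 26.4 kb in Hoxc (chromosome 15, 102962301 to 102988691) ranked next. The Hoxd peak depended on pooling, since the largest single peaks there were 15.3 kb and 15.1 kb in the replicates. Over the whole clusters, peaks covered 81.4 ± 0.267% of Hoxa, 78.1 ± 1.63% of Hoxc, 71.5 ± 0.108% of Hoxd and 57.9 ± 0.226% of Hoxb (SD, n = 2). The Hoxb region ran from Hoxb13 to Hoxb1, and its stretch between Hoxb13 and Hoxb9 held no other Hox gene. No replicated peak lay between 96204070 and 96250248 there. The lower share of Hoxb therefore does not mean shorter coverage at its genes of groups 1 to 9. Their mean covered length was 8.81 kb in Hoxb, against 9.06 kb in Hoxa, 8.68 kb in Hoxc and 8.065 kb in Hoxd.

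Paralogue groups differed in coverage. The 27 genes of groups 1 to 9 had 2997 bp more than the 12 genes of groups 10 to 13 (95% bootstrap interval 1016 to 5019; adjusted p = 0.00255, permutation test), with 2907 bp and 3087 bp in the replicates. Hoxc10 (9.79 ± 0.00778 kb), Hoxd10 (9.56 ± 0.0417 kb) and Hoxa10 (9.05 ± 0.328 kb) were as covered as genes of the lower groups, while the group 13 genes Hoxa13, Hoxb13 and Hoxd13 had 1.3995 ± 0.187 kb, 1.60 ± 0.0693 kb and 1.91 ± 0.0339 kb. The Hoxc cluster differed, with 4.09 ± 0.131 kb at Hoxc13, 7.04 ± 0.122 kb at Hoxc12 and 8.29 ± 0.0502 kb at Hoxc11. At the other end of the clusters Hoxb1 had 1.76 ± 0.0976 kb and Hoxd1 2.23 ± 0.123 kb, and these 8 genes were named after their values were seen. Genes of a cluster share peaks and are not independent, so the p-value is smaller than 4 clusters would support, and the representative TSS of some genes, such as Hoxc5 and Hoxd3, lies at an upstream start within 1 kb of a neighbour's TSS (Hoxc10 and Hoxd4). The difference was not tested with matching on CpG content or without neighbouring TSSs. With each gene's most covered TSS it was 2892 bp. It was 1347 bp with 2.5 kb and 5986 bp with 10 kb either side, and 26737 bp in the width of the widest promoter peak, which in Hoxb is 1 peak shared by 7 genes.

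**Figure D3:**
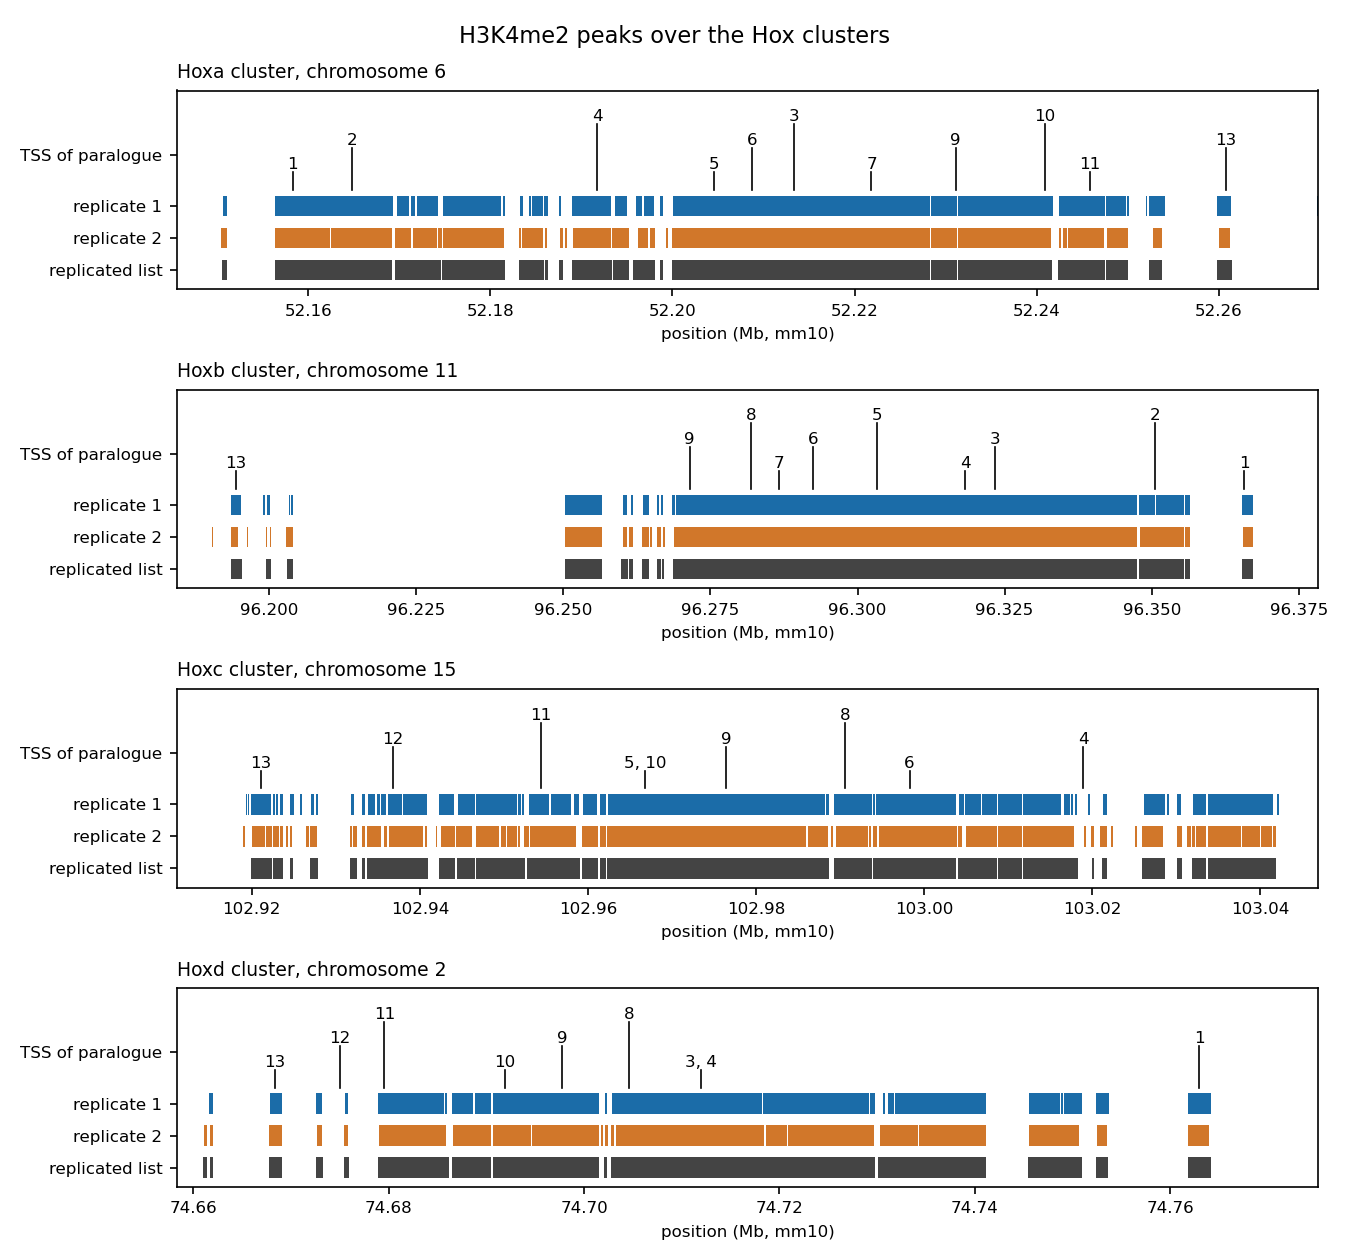
Peaks over the 4 Hox clusters (x axis, position in Mb, mm10; coloured blocks, peaks of replicate 1, replicate 2 and the replicated list; vertical lines, representative TSS of each numbered paralogue). Blocks run almost without a gap across the middle of each cluster, including the 78.9 kb peak of Hoxb, and are short at group 13 of Hoxa, Hoxb and Hoxd.

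Outside the Hox clusters, 13 of the 20 widest replicated peaks lay at promoters. Nfib had a peak of 22.3 kb, Meis2 one of 21.6 kb, Lmx1b one of 19.6 kb, Bcl11a one of 19.2 kb, Lhx5 one of 18.1 kb, Bahcc1 one of 16.9 kb, Ebf3 one of 15.9 kb, and Meis1 and Lhx1 one of 15.9 kb each. Ptch1 and Nr2f1 had peaks of 15.6 kb each, and Zeb2 and the neighbours Rhof and Setd1b peaks of 15.2 kb each. The peak at Bcl11a also covered A830031A19Rik. Meis2, Bcl11a, A830031A19Rik, Lhx5, Bahcc1, Ebf3, Meis1, Ptch1, Nr2f1, Zeb2, Rhof and Setd1b were named after their values were seen. Several of these widths were not reached in the replicates. The largest single peaks in replicates 1 and 2 were 8.85 kb and 11.5 kb at Nfib, 9.45 kb and 7.85 kb at Lhx5, and 9.46 kb and 6.41 kb at Rhof and Setd1b. At Lmx1b the largest in replicate 1 was 12.02 kb, and in replicate 2 those at Bcl11a and Bahcc1 were 10.3 kb and 10.9 kb.

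Distal peaks asked the same question away from promoters. Of the replicated peaks, 20279 lay over 2.5 kb from every protein-coding TSS, and 16117 of them could be assigned to a gene. Some of these may lie at promoters of genes that are not protein-coding, whose TSSs were not used here. Pan-neuronal genes had a mean of 4.81 distal peaks, against 1.61 in random lists matched on territory length. Neural progenitor genes had 4.79 against 1.46, dorsoventral factors 4.09 against 1.28 and spinal neuron factors 3.77 against 1.16. Astrocyte genes (2.62 against 1.09), forebrain and midbrain factors (2.21 against 1.10) and both Hox lists (0.889 against 0.165, and 1.00 against 0.231) were also above random lists, and olfactory receptor genes (0.0344 against 0.248) were below (adjusted p from 5.5e-05 to 0.0330 for these 9 lists, permutation test). These counts depend on the peak list used: in the peaks of replicates 1 and 2 themselves, Hox genes of groups 1 to 9 had a mean of 1.48 in each, and those of groups 10 to 13 had 2.17 and 1.92. The neuronal splicing factor gene Rbfox3 had 20 distal peaks, Pax2 19, Sox2, Lmx1b and Celf4 15 each and Nfib 13; Rbfox3, Pax2 and Sox2 were named after their values were seen.

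The other 13 lists did not pass for distal peaks. Transmitter genes, which had wide promoter coverage, had 0.667 distal peaks against 1.35 in matched random lists (adjusted p = 0.306, permutation test), and 1.67 and 0.8 in the peaks of replicates 1 and 2 themselves. Housekeeping genes had 0.8 against 0.425, oligodendrocyte genes 1.5 against 0.750 and non-neural developmental factors 1.63 against 1.05 (adjusted p = 0.105, 0.0957 and 0.0957, permutation test). The remaining 9 lists, from ganglion, vessel, meninges, microglia, blood, muscle, liver and gut, epidermis and germ cells, had adjusted p-values from 0.239 to 1.00 in the permutation test. Without matching on territory length both Hox calls ended (adjusted p = 0.854 and 0.828; ranges over 6 alternatives 5.5e-05 to 0.854 and 0.00033 to 0.828, permutation test). The call of groups 10 to 13 also ended at 5 kb from every TSS (0.0908), and that of the forebrain and midbrain factors without replicate 2 (adjusted p = 0.0530; range over 6 alternatives 0.00400 to 0.0530, permutation test). Oligodendrocyte genes passed without replicate 2 (adjusted p = 0.0494, range over 6 alternatives 0.0494 to 0.390) and non-neural developmental factors without matching (adjusted p = 0.0217, range 0.0217 to 0.207), by the permutation test. Without replicate 2 the oligodendrocyte genes had 1.29 distal peaks more than random lists. Their means were 2.29 and 1.93 in the peaks of replicates 1 and 2 themselves.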

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

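The tests of microRNA loci and the share of X promoters below the autosomal level were chosen after the result was seen; the other tests of the patterns below were set before their results were computed.

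MicroRNA genes are not part of the protein-coding comparisons, and 3 of the widest intergenic replicated peaks lay at the 3 loci of miR-9, a microRNA of neural progenitors. The peak at Mir9-2 was 21.6 kb wide (chromosome 13, 83712950 to 83734587, ending before the annotated microRNA), the peak at Mir9-1 19.5 kb (chromosome 3, 88203522 to 88223028) and the peak at Mir9-3 17.1 kb (chromosome 7, 79495883 to 79513024). Data left out of the comparisons also held 14 replicated peaks on unplaced scaffolds.

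Listed microRNAs used in neural tissue had 6.30 ± 3.38 kb under peaks within 5 kb either side (SD over 16 loci), against 0.523 ± 0.892 kb at 19 loci of microRNAs known from other tissues, a difference of 5.78 kb (p = 1e-05, the smallest the permutation test can give; adjusted p = 2e-05). Spill-over from protein-coding promoters was argued against, since at the 11 and 9 loci with no protein-coding TSS within 10 kb the difference was 6.71 kb (adjusted p = 0.00027, exact permutation test), and without the miR-9 loci, which prompted the test, 5.77 kb at 8 and 9 loci (adjusted p = 0.000576, exact permutation test). Over all loci without miR-9 it was 4.996 kb (adjusted p = 2e-05, permutation test). The loci were not matched on CpG content, so the part of CpG content in these differences was not tested. A candidate explanation is that these microRNAs are in use in the tissue, which the lists were chosen to represent, but expression was not measured here and the hypothesis was found and tested on the same data.

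Promoter peaks on the X chromosome had lower fold enrichment than autosomal ones, with medians of 19.8 against 34.2 in replicate 1 and 18.7 against 32.7 in replicate 2, a mean ratio of 0.574. Matching on CpG content left the mean ratio of the replicates at 0.599. In the replicated list the matched ratio was 0.575 for X, while the 19 autosomes ranged from 0.955 to 1.05. This argues against CpG content as the whole cause. A few multicopy families were also argued against, since 94.4% of X promoters lay below the autosomal median of their CpG decile. The ratio of 0.574 lies near the lower edge of the range set beforehand for one active X chromosome per cell, and is consistent with that hypothesis. Single X copies in males, an inactive X in females and the handling of the control by the peak caller could each contribute and were not separated.

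Width and fold enrichment picked different promoters. Among the 91 genes with a promoter peak in the progenitor, dorsoventral, spinal neuron, pan-neuronal and transmitter lists, 25 were in the widest 5% of promoters and 1 was in the strongest 5%, where chance gives 4.55 (Fisher's exact test, p = 1.38e-12 and 0.0918). A general loss of fold enrichment with width was argued against, since the 2 measures rose together across 17337 promoter peaks (Spearman rho = 0.542). Genes in the widest 5% had a median fold enrichment of 42.7, against 37.8 over all genes with a promoter peak. Whether fold enrichment falls with width inside the widest 5% was not tested. Whether CpG content sets the fold enrichment was not decided. The rule set beforehand asked only whether choosing within CpG deciles would bring in as many genes as width did. Choosing the strongest 5% within each CpG decile brought in 2 of the 91 genes, against 25 in the widest 5%. That choice therefore did not bring the 2 measures together. Over all genes with a promoter peak, median fold enrichment ranged from 27.9 in CpG decile 4 to 40.4 in decile 8. Width was not matched on CpG content, so the part of CpG content in the 25 wide genes was not tested. The low number among the strongest 5% did not pass. Median fold enrichment was 41.2 in the progenitor list, 34.9 in the pan-neuronal, 29.1 in the transmitter, 26.0 in the dorsoventral and 24.0 in the spinal neuron list. It was 37.8 over all genes with a promoter peak. No biological explanation was tested. A mixture of cell types in which only some carry the mark may lower fold enrichment in the lists below that level and stays open.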

How the results depend on the processing

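The alternatives with the most covered TSS, with CpG matching of occupancy, without neighbouring TSSs and without the 5 most covered spinal cord factors were chosen after seeing the data. Peak location and the 3 differences between lists of factors stayed on the same side of their threshold under all alternatives run for them. The Hox difference was not run with matching on CpG content or without neighbouring TSSs. The mean number of peaks fell from 51509 to 47048.5 at a −log10 q of at least 2, the only alternative run for it. Of the list results for covered length, 194 gave the same call, 4 gained it, 11 lost it and 11 turned. For occupancy these numbers were 108, 6, 11 and 7, and for distal peaks 121, 2, 4 and 5. The covered length of named genes moved by over 1 SD of the replicates for 7 of 102 genes at a −log10 q of at least 2 and for 46 in the replicated list. Leaving out 1 of 2 replicates cannot move a mean that far, so those comparisons say nothing about stability. For the changes below the cause was not tested.

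The share of peaks common to both replicates, 81.6%, was 78.3% when 50% of the shorter peak had to be shared, 83.4% at a −log10 q of at least 2, 93.9% among the stronger 50% of peaks by fold enrichment and 83.9% after merging peaks closer than 500 bp. Promoter occupancy, 68.5%, was 69.8% with promoters of 2.5 kb, 56.8% over the representative TSS itself, 68.1% in the replicated list, 69.0% in the pooled list and 68.2% at a −log10 q of at least 2. Lists with lower covered length numbered 3 in place of 6 with 10 kb either side. Against lists matched on CpG content, lists with higher occupancy numbered 2 in place of 9 and those with lower occupancy 2 in place of 4.

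Directions turned in lists that did not pass, except for the occupancy of dorsoventral factors, whose 95.5% lay below lists matched on CpG content. With that matching the direction also turned for the occupancy of oligodendrocyte (64.3%), non-neural (78.1%), ganglion (80%), muscle (46.2%) and epidermal (58.3%) lists. Covered length against random lists turned for oligodendrocyte genes with 2.5 kb either side (−344 bp) and peak width (−377 bp), for ganglion and Schwann cell genes with 2.5 kb (−2.04 bp) and CpG matching (−42.0 bp), and for mural and meningeal genes with peak width (−207 bp) and between the left-out replicates (−11.4 to 373 bp). Forebrain and midbrain factors turned with 10 kb (395 bp), the replicated list (49.5 bp), the most covered TSS (71.2 bp), no neighbouring TSS (265 bp) and between the left-out replicates (−175 to 157 bp). Oligodendrocyte occupancy was 71.4% with promoters of 2.5 kb. Distal peaks turned for microglia (−0.196), muscle (−0.119) and epidermal genes (−0.0680) without matching, and for erythroid (0.0125) and epidermal genes (−0.0199) at any distance. Depth is unknown and was not varied, so its effect on these results was not tested.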

Other observations

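Genes outside the fixed lists also gathered distal peaks. Skap1, the neighbour of the Hoxb cluster, had 30, Gse1 29, Adgrl2 and Tenm3 22 each, and the transcription factor genes Tcf4 and Ebf1 20 each, all named after their values were seen. Skap2, the neighbour of the Hoxa cluster, had 17. Single neural microRNA loci differed widely: Mir124a-1 had 9.56 ± 0.279 kb under peaks within 5 kb either side and Mir125b-1 9.32 ± 0.301 kb (SD, n = 2), whereas Mir128-1 had 0.00 kb and Mir153 0.626 ± 0.00212 kb. Of the microRNAs from other tissues, the muscle microRNA Mir1a-1 had 3.03 ± 0.0460 kb, the hematopoietic Mir142 2.20 ± 0.0382 kb, and Mir122 of the liver 0.00 kb.

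The replicated list held 2321 peaks (5.80%) that did not overlap a peak in both replicates' own lists by 1 bp, of which 955 met replicate 1 only, 1328 replicate 2 only and 38 neither. These peaks were weak, with a median fold enrichment of 3.28 against 12.96 for the 37699 peaks that met both. The pooled list held 16403 peaks outside the replicated list, with a median fold enrichment of 2.60.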
